A study of Caenorhabditis elegans with 2 samples.

How the data were processed

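The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of MEP-1 carrying an eGFP tag, in whole mixed-stage embryos of Caenorhabditis elegans. The strain carries a mep-1 transgene in an unc-119 mutant background, and the labels give 2 biological replicates of 1 group and a library size range of 150 to 350 bp. A control experiment is named in the labels, and its reads are not used here. The file descriptions name a control alignment for the list of replicate 1 on both builds, for the pooled lists and for the ce10 list of replicate 2, but none for its ce11 list, so whether a control was used for that list is not given in the sources used here. There is no second condition, so no test here compares conditions.

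The deposited files are lists of regions in narrowPeak format on the ce10 and ce11 genome builds. Each replicate has a list of candidate regions that, per the labels, holds peaks and background as input for the irreproducible discovery rate (IDR) procedure. This procedure is meant to keep regions ranked alike in replicates. The pooled reads have a list of the same kind, and the thresholded optimal set is called the IDR set below. Each region carries the authors' deposited signal value, a strength assigned by the peak caller, the −log10 of a q-value, and the position of its summit. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited −log10 q-values have a ceiling that all 2404 peaks of the IDR set on ce11 share, so peaks were ranked by signal value. Signal values were compared within a list only. No list gives read numbers, so the depth of each replicate is unknown, and the exact Clopper-Pearson intervals printed with shares cover counting error over genes or peaks only.

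The files' property that most affects the comparisons is that the IDR set on ce11 is identical to the 2404 strongest regions of the pooled list. The pooled list and the list of replicate 2 both end at 30000 regions, and that of replicate 1 holds 25216. Taking the strongest pooled regions in place of the IDR set, as was intended as a check, therefore repeats the same peaks and gives no separate value. Strong regions are also narrower: 221 IDR peaks were below the usual width of 336 bp, and 94 of the 100 strongest were among them.

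All annotation used ce11, which is WBcel235, with Ensembl release 115 genes, and no coordinate was converted between builds. A summit was in a promoter when it lay from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Remaining summits were assigned in the order 5′ UTR, coding sequence, 3′ UTR, other exon, intron and intergenic. Annotated 5′ ends are taken as they stand, although many worm transcripts are trans-spliced or lie inside operons. Of 361 symbols in the fixed lists, 6 had no match in the annotation and were not analysed.

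The N strongest regions of a replicate, with N = 2404, were matched to the other replicate when they overlapped by at least 50% of both regions. The chance level came from 1000 circular shifts within chromosomes. Genomic context and 6-mers were compared with pooled candidates that overlap no IDR peak, and gene lists with all other protein-coding genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over classes, 25 lists or 2080 6-mers. Noncoding classes were compared with 1000 shifts, two-sided. Peak strength used a permutation test with 100000 resamples and GC content one with 10000. Smallest possible p-values are 0.001 for one-sided shifts, 0.002 for two-sided shifts, 1.0e-05 for peak strength and 1.0e-04 for GC content. Log2 odds have 0.5 added to each cell. Genes and peaks are not independent replicates of the experiment: these p-values describe how peaks are placed, not how a repeat of the experiment would vary.

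Comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes all members of the MEP-1 complex and NuRD list, the protein-coding gene with the nearest 5′ end for the 15 strongest IDR peaks, and up to 4 members of each list with the strongest promoter peak. The alternatives used the 1202 strongest IDR peaks, the 2404 strongest regions of each replicate alone, other promoter windows, other backgrounds, other overlap rules and the ce10 lists. Matching by summits within 100 bp for the IDR set and for signal ranks, signal ranks on ce10, GC-matched and promoter-only sequence references, promoter peaks per 1-Mb bin, a count of each peak for its nearest gene only, a split of the noncoding genes and classes of gene symbols were added after seeing the data. Replicate ranks of named peaks use summits within 100 bp, because narrow regions often fail the rule of 50% of both.

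The steps were tested on simulated data. Over 19973 genes, 100% of planted promoter peaks were assigned to their gene. Each was planted inside the promoter window, so this checks the coordinates and not whether a peak belongs to a neighbouring gene. Of 200 random lists, 5.5% passed an unadjusted threshold of 0.05. With 60.4% of 2404 regions planted as shared, 60.6% were found. The planted copies kept their width and moved only slightly, so this does not test the matching of regions that differ in width. A planted 6-mer ranked 1 of 2080. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.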

Results

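MEP-1 is a zinc-finger protein that works with the chromatin remodeller LET-418, the worm Mi-2, and with the histone deacetylase HDA-1, and it is known for keeping germline genes off in somatic cells. The data are candidate regions, background among them, and a thresholded peak set for eGFP-tagged MEP-1 in mixed-stage embryos, from 2 biological replicates. The median −log10 q-value on ce11 was 0.227 in the pooled candidate list, against 3.695 in the IDR set. The lists hold 25216 candidate regions for replicate 1, 30000 for replicate 2 and 30000 for the pooled reads, and the IDR set on ce11 holds 2404 peaks. On ce10 the IDR set holds 2513 peaks. Coordinates are on ce11, and read depth is unknown.

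The locus of mep-1 itself was examined first, because the strain carries extra mep-1 sequence. The gene lies on chromosome IV from 11524642 to 11527954. No candidate region of any list, and so no IDR peak, had its summit within 20 kb of the gene. Random windows of the same 43313 bp held a median of 13 pooled candidates, and the mep-1 window stood at percentile 1.07 for summed pooled signal, or 7.6 with 5 kb on each side. It stood at percentile 0.28 in replicate 1 and 0.84 in replicate 2. The gap around the gene spanned 60.3 kb in replicate 1 and 58.3 kb in replicate 2. For the IDR set alone, whose random windows held a median of 1 peak, the window stood at percentile 19.9. These percentiles place the window in the middle of its ties, so the share of random windows that were as empty is larger than the percentile. The lists carry no value for mep-1 in this gap, so they do not show whether the protein binds there.

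The replicates share many of their strongest regions, far more than chance. Of the 2404 strongest regions of replicate 1, 1179 (49.0%) overlapped the corresponding set of replicate 2, and 1165 (48.5%) did so in the other direction. Circular shifts gave 0.792% ± 0.175 (SD over 1000 shifts) for the first direction, with a one-sided p of 0.001, the smallest the shifts allow. An overlap of at least 1 bp gave 58.1% and 56.2%, and summits within 100 bp gave 50% in each direction. Among the 250 strongest regions the share was 20.4% by this rule, against 42% when summits within 100 bp were matched; 159 of the 250 strongest regions of replicate 2 were narrower than usual, and a narrow region can fail the rule of 50% of both. Of those 250 regions of replicate 1, 242 had a summit match somewhere in the list of replicate 2. Across 7469 matched regions, the signal values of the replicates had a Spearman rho of 0.539, a value across regions, which are not independent.

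**Figure D1:**
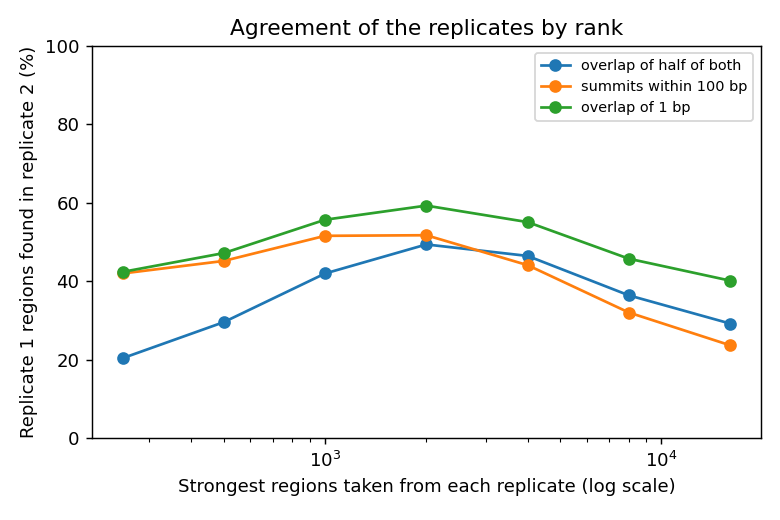
Share of the strongest regions of replicate 1 found among as many strongest regions of replicate 2 (vertical axis, percent), against the number of regions taken (horizontal axis, log scale), under 3 matching rules drawn as lines with a point per number. At 250 regions the rule of 50% of both gives 20.4% and summit matching 42%; at 2000 regions they give 49.4% and 51.8%.

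The IDR set held more of the strongest regions of replicate 2 than of replicate 1. Of its 2404 peaks, 2130 (88.6%) were among the strongest regions of replicate 2 and 1324 (55.1%) among those of replicate 1, with 1139 found in both and 991 in replicate 2 alone. Anywhere in the full lists, 2032 peaks (84.5%) had a summit match within 100 bp in replicate 1 and 2367 (98.5%) in replicate 2. Peak signal in the pooled list had a Spearman rho of 0.922 with the signal of replicate 2 and 0.579 with that of replicate 1, where summits matched.

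All of the 15 strongest peaks had their summits in promoters. The strongest, with a signal of 357.3, spanned 10563462 to 10563708 on chromosome II, with its summit 182 bp upstream of cdc-48.1, a AAA ATPase that extracts ubiquitinated proteins. The next lay on chromosome III from 3867454 to 3867707, upstream of the ribosomal protein gene rpl-3, with a signal of 356.3. Among the 15 strongest were also peaks at rpl-35 (274.5), rpl-15 (268.9), rps-15 (219.7), the translation factor gene iff-2 (256.4) and the Hsp70 chaperone gene hsp-1 (219.2). The peak nearest to Y17G9B.5 (311.7) also lies in the promoter of rpl-20, and the peak nearest to ska-3 (240.1) also lies in that of rps-12. The others were nearest to tasp-1 (322.5), K12H4.5 (282.3), Y71H2AM.20 (246.5), C47E8.4 (236.2), puf-9 (217.9), which encodes a Pumilio-family RNA-binding protein, and W08E12.7 (214.0). Their ranks differed between replicates: the cdc-48.1 peak ranked 1 in replicate 2 and 62 in replicate 1, and the puf-9 peak 11 and 452.

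Peak summits lay in promoters more often, and in coding sequence less often, than those of other candidates. Of 2404 summits, 1629 (67.8%, 95% interval 65.9 to 69.6) were in a promoter, against 23.5% of the 27338 pooled candidates outside IDR peaks, an odds ratio of 6.84. Shifted peaks fell in promoters in 21.1% ± 0.824 (SD) of cases (permutation by circular shifts, two-sided p = 0.002, the smallest possible). Only 5 summits (0.208%) lay in coding sequence, against 9.61% of candidates (adjusted p = 2.5e-91, Fisher's exact test). With the strongest regions of replicate 1 alone, the log2 odds were 2.13 for promoters (2.77 with the IDR set) and -1.43 for coding sequence (-5.54 with the IDR set), so the size of the coding deficit depends on the replicate. Introns held 10.8% of summits against 35.5% of candidates (Fisher adjusted p = 1.1e-157), and intergenic sequence 14.8% against 24.3% (adjusted p = 3.4e-28). The 3′ UTR held 4 summits (Fisher adjusted p = 2.0e-22), and the 5′ UTR class, with 15 summits, did not pass the test (adjusted p = 0.081). Other exons, which include those of noncoding genes, held 5.66% against 3.31% (Fisher adjusted p = 2.5e-08), a difference that did not pass among the 1202 strongest peaks (adjusted p = 0.17).

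**Figure D2:**
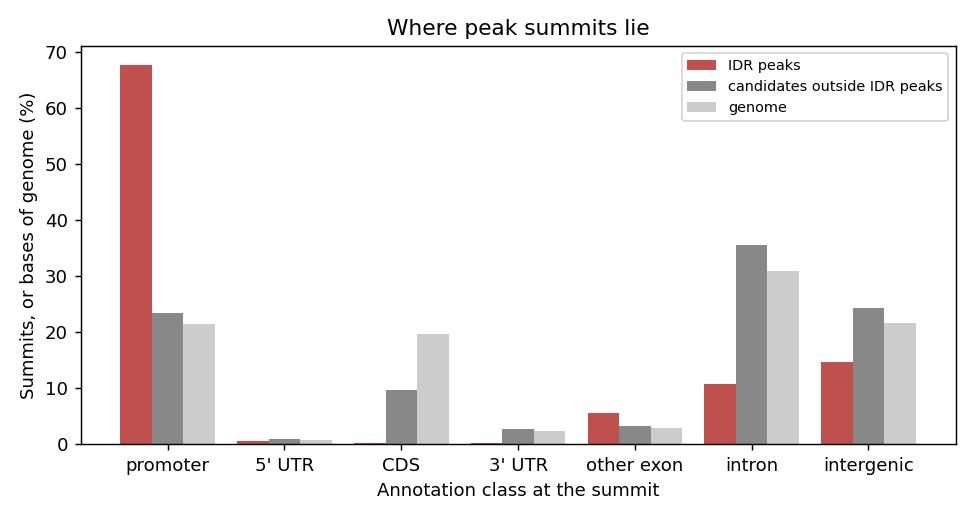
Percent of summits (vertical axis) in each annotation class (horizontal axis) for the 2404 IDR peaks and for the 27338 pooled candidates outside them, with the percent of genome bases in each class. Promoters hold 67.8% of IDR summits, 23.5% of candidate summits and 21.5% of the genome.

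The summit lay upstream of the nearest 5′ end in 78.9% of peaks, with a median signed distance of -177 bp. In 564 cases the summit was in the promoters of a pair of genes on opposite strands. In all, 2275 of 19973 protein-coding genes (11.4%) had a promoter peak. For 1295 of these (56.9%) the strongest such peak lay in the promoter of another gene too. So it did for 45 of 67 ribosomal protein, 17 of 23 proteasome, 9 of 13 small RNA pathway, 9 of 11 P granule and 8 of 9 chemoreceptor genes with a peak. Other lists had lower shares, among them synMuv and DREAM (5 of 10), nuclear hormone receptors (3 of 10), vacuolar ATPase (2 of 7) and dosage compensation (1 of 7). These shares were not tested against each other. Of the 80 list members with a promoter peak that are named below by rule, 24 had the summit nearer to another gene's 5′ end. Promoter peaks were stronger than the others, with a median signal of 56.1 (interquartile range 35.2, n = 1629) against 46.9 (20.7, n = 775), and the permutation p was 1.0e-05, the smallest possible.

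Genes with promoter peaks were more frequent in chromosome centres and slightly less frequent on X. In the central 50% of chromosomes, 12.5% of genes had a promoter peak, against 9.99% in the outer 25% at each end (Fisher's exact p = 1.8e-08). On X, 268 of 2731 genes (9.81%) had one, against 11.6% of autosomal genes (Fisher p = 0.0048). Counting all IDR peaks, inside promoters or not, 1-Mb bins averaged 24.5 ± 5.11 (SD, n = 17 bins) on X and 23.8 ± 10.2 (n = 80) on autosomes, with a permutation p of 0.81. Promoter peaks alone, a count chosen after seeing the data, averaged 13.5 ± 3.86 and 16.8 ± 7.74 per bin (permutation p = 0.096). Among autosomes the share of genes ran from 7.03% on V to 17.4% on III.

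Among the 25 gene lists, 9 had a higher share of members with a promoter peak than other protein-coding genes and 7 a lower share (Fisher's exact test, adjusted over the lists). Ribosomal protein genes stood highest where a shared peak counts for each gene, with 67 of 79 (84.8%, 95% interval 75 to 91.9) against 11.1% of other genes (Fisher adjusted p = 4.1e-50). Their strongest peaks were those of rpl-3, rpl-20, rpl-35 and rpl-15. Of the proteasome subunit genes, 23 of 33 (69.7%) had a promoter peak (Fisher adjusted p = 4.4e-14), led by rpn-3 (210.5), rpn-9 (106.2), pas-4 (105.3) and rpn-12 (98.1). Of the replication and cell cycle genes, 17 of 34 (50%) did (Fisher adjusted p = 1.9e-07), including cye-1, which encodes cyclin E (113.5), pcn-1, which encodes PCNA (95.4), wee-1.3 (73.0) and cdk-4 (67.9). Genes of the dosage compensation list, many of which act to lower X-linked transcription in hermaphrodites, had a promoter peak in 7 of 12 cases (Fisher adjusted p = 2.9e-04), led by sdc-2 (67.0), mix-1 (62.7), dpy-26 (57.5) and dpy-27 (53.96).

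Lists of chromatin, small RNA and germline regulators also had a higher share when a shared peak counted for each of its genes. Of the synMuv and DREAM genes, many of which repress transcription, 10 of 25 (40%) had a promoter peak (Fisher adjusted p = 5.3e-04). The strongest were at lin-54 (178.6), efl-1 (150.7), lin-35, the worm retinoblastoma gene (127.0), and lin-53 (115.2). Small RNA pathway genes had one in 13 of 41 cases (31.7%, Fisher adjusted p = 8.8e-04), led by mut-15 (124.6), rde-4 (93.2), nrde-2 (91.5) and nrde-4 (89.1). P granule and germ cell fate genes had one in 11 of 39 (28.2%, Fisher adjusted p = 0.0064), led by ifet-1 (202.6), cgh-1 (138.4), mes-2 (93.7) and mex-1 (89.4). Vacuolar ATPase subunits had one in 7 of 20 (Fisher adjusted p = 0.0089), with vha-8 (189.1), vha-1 (114.6), vha-12 (91.6) and vha-15 (73.6) the strongest. Heat shock protein genes had one in 7 of 22 (Fisher adjusted p = 0.014), with hsp-1, hsp-110 (210.5), hsp-60 (141.6) and hsp-3 (110.4) the strongest. When only genes with a pooled candidate in the promoter formed the background, the calls ended for the synMuv (Fisher adjusted p = 0.065), small RNA (0.093), vacuolar ATPase (0.2) and heat shock (0.076) lists. The P granule call ended with the narrower promoter window (Fisher adjusted p = 0.23). Several of these leading peaks lie nearer to the 5′ end of another gene, named here after seeing the values: the lin-54 summit is at -36 bp from rpl-12, the ifet-1 summit at -264 bp from rps-1, the mut-15 summit at -91 bp from fib-1, and the hsp-110 peak is the rpn-3 peak. The lin-53, mex-1, nrde-2, vha-8, vha-1 and hsp-60 summits also lie nearer to another gene's 5′ end. In an alternative chosen after seeing the data, each peak counted only for the nearest of the genes whose promoter holds it. The P granule list then had 6 of 39 (Fisher adjusted p = 0.21), the small RNA list 7 of 41 (0.085) and the heat shock list 3 of 22 (0.52), none past the threshold, while the synMuv list had 8 of 25 (0.0016) and the ribosomal protein list 39 of 79 (4.8e-21). At 49.4%, the ribosomal protein list then stood below the dosage compensation (58.3%) and proteasome (54.5%) lists.

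Of 10 measured genes of the list that joins the MEP-1 complex and NuRD, hda-1 (39.3) and lin-53 (115.2) had a promoter peak. Both summits lie nearer to another 5′ end: that at hda-1 is at -970 bp, outside the narrow window, and at -290 bp from ril-1, and that at lin-53 is at -245 bp, and at -222 bp from nra-2. The share is 20% against 11.4% of other genes, and the list did not pass the test (Fisher adjusted p = 0.36). No promoter peak was listed at let-418, chd-3, hda-3, lin-40, rba-1, dcp-66 or mbd-2, and mep-1 lies in the gap described above. With the wide promoter window, dcp-66 and rba-1 gained a peak, and the list still did not pass (Fisher adjusted p = 0.056). The peak gained by rba-1 is the one at lin-53, so in this setting 1 peak counts for 2 members. Of the SUMO pathway genes, which attach the small protein SUMO to others, 3 of 10 had a peak, ubc-9 (77.3), smo-1 (54.8) and uba-2 (43.8), with a Fisher adjusted p of 0.13. The log2 odds of this list were 1.86, and 0.58 with the strongest regions of replicate 1 alone. The uba-2 summit is at -303 bp, and at -10 bp from vps-25.

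Large families of receptor, secreted and structural genes had few promoter peaks. Chemoreceptor genes had them in 9 of 1316 cases (0.684%, against 12.1% of other genes, Fisher adjusted p = 5.6e-56). The strongest were at srh-16 (114.4), sri-5 (96.3), sre-23 (92.4) and str-12 (88.6). C-type lectin genes had 5 of 240 (Fisher adjusted p = 5.2e-07; clec-140, clec-53, clec-87 and clec-104 strongest) and F-box genes 11 of 322 (adjusted p = 1.4e-06; fbxa-90, fbxb-85, fbxb-58 and fbxa-153 strongest). The fbxa-90 summit is the one at efl-1, and the fbxa-153 peak is the str-12 peak. Cuticle collagens had 3 of 174 (Fisher adjusted p = 1.1e-05; col-38, col-71 and col-185), nuclear hormone receptors 10 of 269 (adjusted p = 3.3e-05; nhr-47, nhr-1, nhr-32 and nhr-142 strongest), neuropeptide genes 2 of 140 (adjusted p = 3.5e-05; ins-39 and flp-23) and major sperm protein genes 0 of 44 (adjusted p = 0.013). With the background of genes that hold a pooled candidate, the C-type lectin (Fisher adjusted p = 0.48) and major sperm protein (0.61) calls ended. The latter also ended with the narrow promoter window (Fisher adjusted p = 0.05), among the 1202 strongest peaks (0.17) and with each peak counted for its nearest gene only (0.085). These shares are low relative to other genes. Against randomly shifted peaks, the chemoreceptor list alone was lower, with 9 genes against 29.0 ± 5.57 (SD, adjusted p = 0.0045, permutation by circular shifts).

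The other lists were not called. Histone genes had 13 of 72 members with a peak, on 8 distinct peaks (Fisher adjusted p = 0.13), with his-67 and his-68 sharing a peak of 182.5, his-37 at 147.4 and his-31 at 104.6; the list passed among the 1202 strongest peaks (0.0052) and with the narrow promoter window (0.037). Against shifted peaks the histone and SUMO lists passed (permutation by circular shifts, adjusted p = 0.0045 and 0.0083), but peaks in general fell in promoters more often than shifted ones, so this does not set the lists apart from other genes. Meiosis genes had 3 of 29 (Fisher adjusted p = 1), brc-1, him-17 and rad-51. The rad-51 peak had no summit match within 100 bp in the list of either replicate. Among the other list members named by rule, the peaks of hsp-3, uba-2, pop-1 and pat-4 had none in replicate 1. Embryonic lineage transcription factors had 1 of 37, pop-1 (35.1; Fisher adjusted p = 0.15), and homeobox genes 6 of 99 (adjusted p = 0.15), with ceh-38, ceh-20, ceh-39 and ceh-100 the strongest. Both lists passed as lower with the wide promoter window (Fisher adjusted p = 0.049 for each), and homeobox genes also with the background of genes that hold a pooled candidate (0.0068). Muscle genes had 4 of 43 (act-2, unc-112, unc-60 and pat-4; Fisher adjusted p = 0.85), neuron and synapse genes 2 of 47 (syd-2 and snb-1; adjusted p = 0.2) and intestine genes 1 of 28 (erm-1; adjusted p = 0.4).

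**Figure D3:**
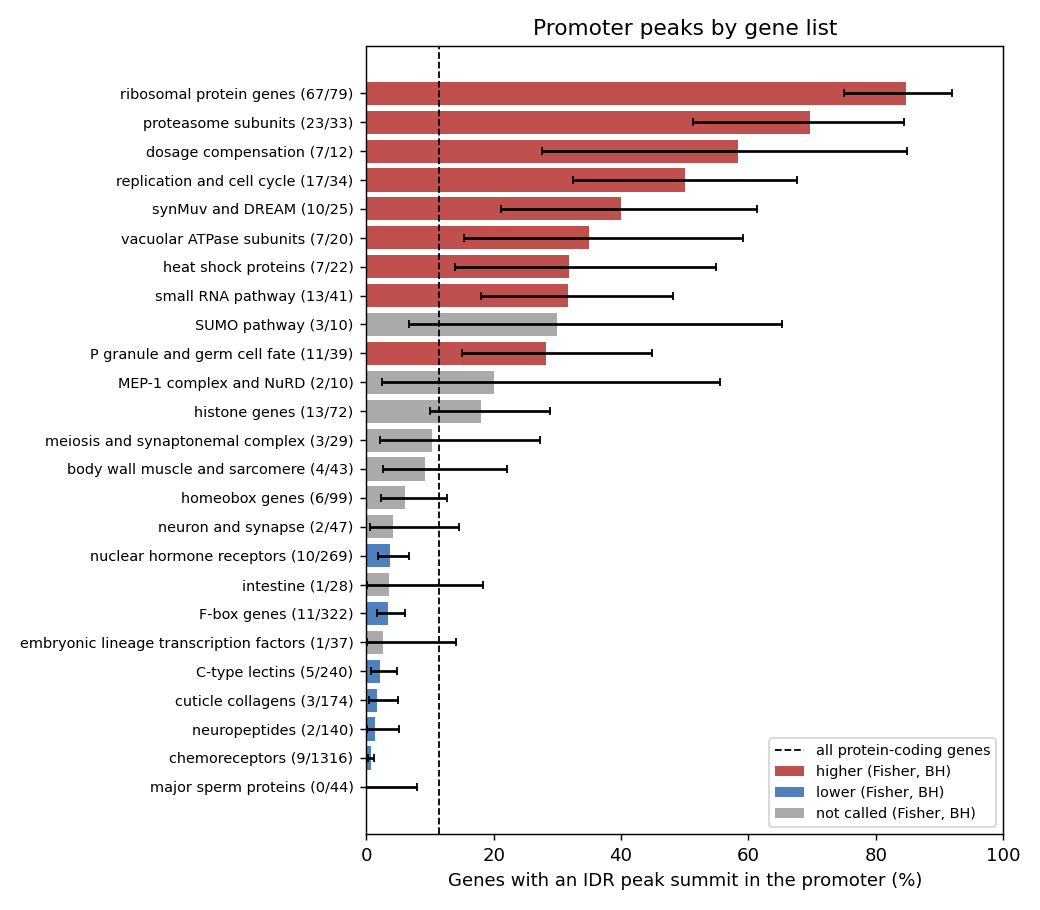
Percent of the members of each gene list with an IDR peak summit in the promoter (horizontal axis), with exact 95% intervals as bars and counts beside each list; colours give lists higher, lower or not called by Fisher's exact test with Benjamini-Hochberg adjustment. Ribosomal protein genes reach 84.8%, the dashed line marks 11.4% for all protein-coding genes, and chemoreceptors lie at 0.684%.

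Genes for small structural RNAs also had peaks more often than shifted summits gave. Of 612 tRNA genes, 107 (17.5%) had a summit from 500 bp upstream to their 3′ end, against 8.56 ± 3.11 (SD) with shifted peaks. Of 346 snoRNA genes, 66 did, against 5.45 ± 2.46, and of 129 snRNA genes, 13 did, against 1.78 ± 1.38. Permutation by circular shifts gave the 3 classes an adjusted p of 0.0028, as did miRNA genes (23 of 261 against 3.71 ± 2.09) and the pooled other noncoding genes (490 of 23227 against 284.6 ± 30.05). lincRNA genes had 17 of 194 against 7.88 ± 2.75 (same permutation, adjusted p = 0.014), and none of 20 rRNA genes had a summit (adjusted p = 1). Peaks in general fell in promoters more often than shifted ones, so an excess over shifts alone does not set these classes apart. The tRNA result came from 99 distinct peaks, of which 80 were outside protein-coding promoters, while 33 of the 66 snoRNA peaks were inside them.

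Sequence at the summits was richer in G and C than at other candidates. GC content of 100 bp averaged 47.8% ± 6.63 (SD, n = 2404 peaks) against 37.2% ± 9.23 (n = 27338), a difference of 10.5 percentage points (permutation p = 1.0e-04, the smallest possible). Of 2080 6-mers, 775 were more and 631 less frequent in peaks by Fisher's exact test. The leading one, GAGCGC or its reverse complement, was in 18.3% of peaks and 2.77% of candidates (Fisher, odds ratio 7.86, adjusted p = 1.6e-177). ACGCGC followed (17% against 2.55%), and the GA repeat GAGAGA was in 28.1% against 10.5%. The A- and T-rich AAAATT was in 17.5% against 42.7%. With the strongest regions of replicate 1 alone, the log2 odds fell from 2.97 to 1.69 for GAGCGC and from 2.97 to 1.88 for ACGCGC. Against GC-matched candidates, an alternative chosen after seeing the data, 339 6-mers were more frequent. The log2 odds of the 15 leading 6-mers then ran from 0.82 for GAGAGA (1.74 before) to 2.13 for GAGCGC. Between promoter summits of both sets, also chosen after seeing the data, 577 were more frequent, with log2 odds of 1.13 for GAGAGA and 2.73 for GAGCGC.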

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

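In data outside the comparisons, the list of replicate 1 holds 24 regions on the mitochondrial chromosome, and the list of replicate 2 holds 0. The strongest of them, with a signal of 90.3, ranks 1 of the 25216 regions of replicate 1. No explanation was tested, and the 24 regions entered no nuclear comparison.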

How the results depend on the processing

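The summit matching for the IDR set and signal ranks, the GC-matched reference, promoter peaks per 1-Mb bin and counting a peak for the nearest gene only were chosen after seeing the data. The promoter share, the chromosome centre difference, promoter peak strength, the number of noncoding classes, the GC difference and the replicate overlap kept their direction and side of the threshold under each alternative run. For the values below that moved or changed sign, the cause was not tested except where stated. The IDR peaks found in replicate 1 and replicate 2 came to 63.3% and 90.9% with 1 bp of overlap, 65.6% and 95.1% for the 1202 strongest peaks, and 58.5% and 90.0% by summits within 100 bp. The signal rho was 0.263 for regions that overlap an IDR peak, a narrower range of signal, and 0.613 by summits. The X difference turned to a log2 ratio of 0.038 per 1-Mb bin, where all IDR peaks are counted, and was -0.31, not past the threshold, for promoter peaks per bin. Lists with a higher share numbered 5 with the candidate background, which tests fewer genes, and lists with a lower share 1 against shifted peaks. With the nearest gene only, the MEP-1 complex and NuRD list turned to a log2 odds of -0.89. Against shifts, log2 values turned positive for homeobox genes (0.92), nuclear hormone receptors (0.65), muscle (1.39), neuron and synapse (0.37), intestine (0.27) and F-box genes (0.26). Muscle lay between 0.48 and 0.97 with a single replicate, at 0.14 with the narrow and 0.0074 with the wide promoter window. Meiosis lay between -0.45 and 0.75 with a single replicate, at -0.39 with the wide window and at -0.66 with the candidate background. The 6-mers less frequent in peaks numbered 419 to 643 with a single replicate, and those more frequent 339 against GC-matched candidates. Of 99 named genes, the promoter peak call changed for 3 with replicate 2 alone, 11 with replicate 1 alone, 10 with the 1202 strongest peaks and 19 with the narrow window, each a loss, and 2 were gained with the wide window. No paired analysis was possible because there is 1 group. The unknown depth limits what a missing peak means.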

Other observations

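The tests on gene symbol classes, noncoding subclasses, the mep-1 gap, the region widths and GC content among the 250 strongest regions were chosen after their results or related values were seen. Among 240 classes of gene symbols with at least 8 members, 27 had promoter peaks more often and 21 less often than other genes (Fisher's exact test, adjusted over classes). Beyond the ribosomal and proteasome genes, the first included nuclear pore genes of the npp class (15 of 26, Fisher adjusted p = 7.3e-07; npp-8 the strongest at 133.8), translation initiation factors of the eif class (14 of 25, adjusted p = 3.1e-06; eif-3.C at 153.5) and mitochondrial ribosomal protein genes of the mrpl class (18 of 41, adjusted p = 4.4e-06; mrpl-55 at 112.7). Chaperonin subunits of the cct class (7 of 8, Fisher adjusted p = 4.3e-05; cct-1 at 151.8), SR splicing factors of the rsp class (7 of 8, adjusted p = 4.3e-05; rsp-6 at 171.0) and RNA polymerase II subunits of the rpb class (7 of 11, adjusted p = 6.1e-04; rpb-11 at 120.6) were also among the 27. Of the cytochrome P450 class cyp, 0 of 74 genes had a promoter peak (Fisher adjusted p = 0.0026).

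Noncoding subclasses differed in direction. Genes annotated as ncRNA had a summit in 425 of 7764 cases against 119.4 ± 11.8 (SD) with shifted peaks, while piRNA genes had 59 of 15363 against 161.8 ± 28.1 and pseudogenes 18 of 2128 against 89.5 ± 9.30, each with an adjusted p of 0.0027 by permutation with circular shifts. Antisense RNA genes had 6 of 100 (adjusted p = 0.25, same permutation). As for the noncoding classes above, an excess over shifts alone does not set a subclass apart. Away from protein-coding 5′ ends, 424 peaks lay beyond 2000 bp. The strongest of these ranked 20, on chromosome X from 11094095 to 11094329, in intergenic sequence.

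The ribosomal protein gene peaks were weighed against base composition and against signal that follows transcription. Among 8185 promoter candidates, those at ribosomal protein genes were in the IDR set with an odds ratio of 19.1, and of 11.1 (95% interval 5.55 to 22.4) within bins of GC content, so GC content alone does not remove the pattern. If signal spread along transcribed genes, gene bodies should hold candidates too. Ribosomal protein genes held 0.305 candidates per kb of body against 0.318 in other genes with a promoter peak, a ratio of 0.960 (95% interval 0.495 to 1.68), which does not decide. Open chromatin at active promoters may contribute, and no biological explanation was tested, since there is 1 group.

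The empty interval around mep-1 was weighed against chance and against the transgene. Of 10000 random windows of equal length with at least as many protein-coding genes, 0.27% were empty in the pooled list and both replicates, which argues against a gap of the ordinary kind. The gap shared by the lists spanned 58.3 kb. Extra copies of this sequence in the control reads could raise the background there and remove candidates, a possibility that stays open because control reads are not used here and no control alignment is named for the ce11 list of replicate 2, which has the gap as well.

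The low overlap of the 250 strongest regions of each replicate was weighed against region width and base composition. Matching by summits raised the share from 20.4% to 42% (95% interval 35.8 to 48.4), still below the 51.6% for the 1000 strongest regions. The matching rule is therefore not the whole of the difference. By summits the share was also lower, at 44.1%, for the 4000 strongest regions, so it varies with the number taken. A lower share for 250 regions need not have a further cause. Among those 250, the mean GC of regions without a summit match in the other replicate's 250 differed by -4.48 percentage points (95% interval -5.92 to -3.04), replicate 1 minus replicate 2, at 46.7% ± 6.40 (SD, n = 145) and 51.2% ± 6.12 (n = 145). In the wider set of the 2404 strongest regions, regions without any overlap in the other replicate differed by -5.55 percentage points (95% interval -6.22 to -4.89), at 42.1% ± 7.70 (SD, n = 1008) and 47.7% ± 7.73 (n = 1054). A GC-dependent difference between the libraries may contribute, and so may a difference in depth, which is unknown. Candidates outside IDR peaks had a lower mean GC (37.2%) than IDR peaks (47.8%). More background among the regions of replicate 1 would give the same sign, so the GC values alone cannot tell the explanations apart. Of the 250 strongest regions of replicate 1, however, 242 had a summit match somewhere in the list of replicate 2. This match argues against background found in replicate 1 alone as the main source of those 250. Background shared by both lists stays open.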
